A study of Mus musculus with 14 samples.

How the data were processed

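Expression was measured with an Affymetrix mouse array in total RNA labelled as striatum of R6/2 and wild-type mice on a CBA by C57BL/6 background. The 14 arrays were grouped by the genotype in the labels, 7 R6/2 and 7 wild-type. The start of each sample title, M.C or Mith, was taken as a cohort, since the labels describe control groups for 2 drug studies. The M.C cohort held 4 arrays of each genotype and the Mith cohort held 3 of each. Replicates are numbered in the order of the record, so that replicates 1 to 4 of each genotype belong to M.C and replicates 5 to 7 to Mith.

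The deposited table holds log2 probe set signals for 22690 probe sets. The unit was read from the values, which ran from 2.96 to 14.5 with none missing. How the authors summarised and normalized the arrays is not given in the sources used here. The 64 control probe sets were left out and 22626 were tested. The medians of the deposited log2 values ran from 7.07 to 7.17, a span of 0.108. A rule fixed before the data were examined kept the deposited scale up to a span of 0.1, so each array was centred on a common median. No raw scans were used here, so background and probe level noise were not modelled.

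Gene symbols came from the platform's probe table and were brought up to date by gene ID with a mouse gene table. 20380 probe sets carried 1 symbol, 691 carried several and 1555 were unnamed. 20351 symbols were matched by gene ID and 29 were kept as the platform gives them. Each of 12393 genes was represented by its probe set of highest mean over the 14 arrays. Probe sets marked as cross-hybridising were passed over where the gene had another. All other probe sets of a named gene were looked at for direction.

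Genotype was tested per probe set with limma 3.58.1 in R 4.3.3, with genotype and cohort as terms and moderated variances. The moderated test was two-sided, and a call is a Benjamini-Hochberg adjusted p under 0.05 over all 22626 probe sets. Genotype was also tested within each cohort. An interaction of genotype with cohort was fitted, and the cohorts were compared with genotype as a term. Fold changes of the within-cohort fits were compared across genes with Pearson and Spearman correlations, which have no independent replicates, and 100 permutations of genotype within cohorts gave the chance range.

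Named genes followed a rule fixed in advance. It took the 12 largest falls and 12 largest rises among called genes of the same sign in both cohorts, leaving out clone and predicted names. It added up to 3 called members of each gene list with the smallest p. It always took Ppp1r1b, Drd1, Drd2, Penk, Tac1, Adora2a, Pde10a, Cnr1, Bdnf, Ppargc1a and Htt, and the 5 largest called changes each way between cohorts and in the interaction. Drd1 and Adora2a had no probe set with a single symbol here. Other members of the lists that are quoted (Homer1, Nr4a1, Dusp1, Fos, Pdyn, Isl1, Mag, Cnp, Mog, Mbp, Aspa, Pde1b, Rgs9, Meis2, Bcl11b, Prkcd, Lhx9, Slc17a6, Slc1a3 and Gja1) were chosen after their values were seen.

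The 31 gene lists, 471 genes of which 387 had a named probe set, were also fixed in advance. They cover shared, direct-pathway and indirect-pathway striatal projection neuron genes, and genes of interneurons, astrocytes, mature oligodendrocytes, oligodendrocyte precursors, microglia and vessels. Neighbouring tissue and blood were covered by cortical glutamatergic, thalamic, choroid plexus and erythroid genes. Pathway lists covered immediate early, glucocorticoid-responsive and circadian genes, glutamate receptors, GABA receptors, potassium channels, calcium handling, synaptic vesicle genes, cholesterol synthesis, heat shock, the unfolded protein response, proteasome subunits, respiratory chain subunits, glycolysis, ribosomal proteins, developmental transcription factors, interferon-stimulated genes and p53 targets. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 31 lists, and again with an estimated correlation and with fry. Counts of members were adjusted over all probe sets and over the list alone. Differences between lists were tested by exact two-sided permutation of genotype within cohorts, 1400 arrangements, after the data had been seen.

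Array quality was described by 8 measures. They were the deposited median, the spread of log2 values, the mean Spearman correlation with the other arrays of the cohort, the 3′ minus 5′ difference of the Actb and Gapdh control probe sets, the 18S control, Xist and Ttr. Each was compared between genotypes by an exact two-sided permutation test of 7 against 7, 3432 arrangements, and by the same test within cohorts.

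Alternatives covered no cohort term, quantile normalization, the values as deposited, brighter probe sets, trended and robust variances, array weights, the Actb 3′ minus 5′ difference or the Xist level as a covariate, each cohort alone, 1 probe set per gene, a threshold of 0.01, the mean of a gene's probe sets and each array left out in turn. Other assignments of the arrays to groups were also fitted.

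The procedure was tested on simulated data of the same size, with 100 probe sets changed by 0.5 and 100 by 1 on the log2 scale. With cohort as a term, 90 and 100 of these were recovered. Within M.C 71 and 99 were recovered, within Mith 34 and 96, for the interaction 31 and 87 and for the cohort difference 88 and 100. Between 5 and 8 unchanged probe sets were called in each comparison. All 5 lists shifted by -0.25 and 0 of 25 unchanged lists were called. The simulated noise was independent between genes, while members of real lists were correlated (0.649 estimated for shared projection neuron genes). The simulation therefore does not give the rate of false list calls in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.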

Results

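Gene expression was measured by array in the striatum of R6/2 mice and wild-type controls at 6 weeks of age. R6/2 mice carry a transgene with exon 1 of the human HTT gene with an expanded CAG repeat and are used as a model of Huntington disease. All animals had received normal saline 30 to 60 minutes before sacrifice and served as control groups for 2 drug studies. The arrays formed a cohort with titles starting M.C, 4 R6/2 and 4 wild-type, and a cohort with titles starting Mith, 3 R6/2 and 3 wild-type. The number of arrays limits the precision of every value. The labels refer to animals but do not say that each array is a separate animal, so p-values measure the spread between arrays. Fold changes are log2 values, R6/2 minus wild-type with cohort as a term, on 7 arrays per genotype unless a cohort is named, and ± gives the SE.

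The arrays separated first by cohort. Component 1 held 43.1% of the variance and parted M.C from Mith, and component 2 held 13.8%. R6/2 replicate 4 stood apart from its cohort, with a mean Spearman correlation of 0.981 with the other M.C arrays, the lowest of all arrays. The Actb 3′ minus 5′ difference, a measure of RNA quality, was 0.608 ± 0.181 (SD, n = 7) in R6/2 and 0.373 ± 0.143 (SD, n = 7) in wild-type, exact permutation p = 0.0210. Within cohorts the exact p was 0.0186, and adjusted over the 8 quality measures the exact values were 0.128 and 0.0743. The means were 0.577 against 0.324 in M.C and 0.649 against 0.439 in Mith. The Gapdh difference was also larger in R6/2, by 0.191 with exact p = 0.0321 and adjusted p = 0.128, and within cohorts the exact p was 0.0143, adjusted 0.0743. The Gapdh means were 0.337 against 0.053 in M.C and 0.058 against -0.0095 in Mith. Xist, a transcript of female cells, was high on every array, from 10.4 to 11.2, and did not differ by genotype, exact p = 0.712.

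**Figure D1:**
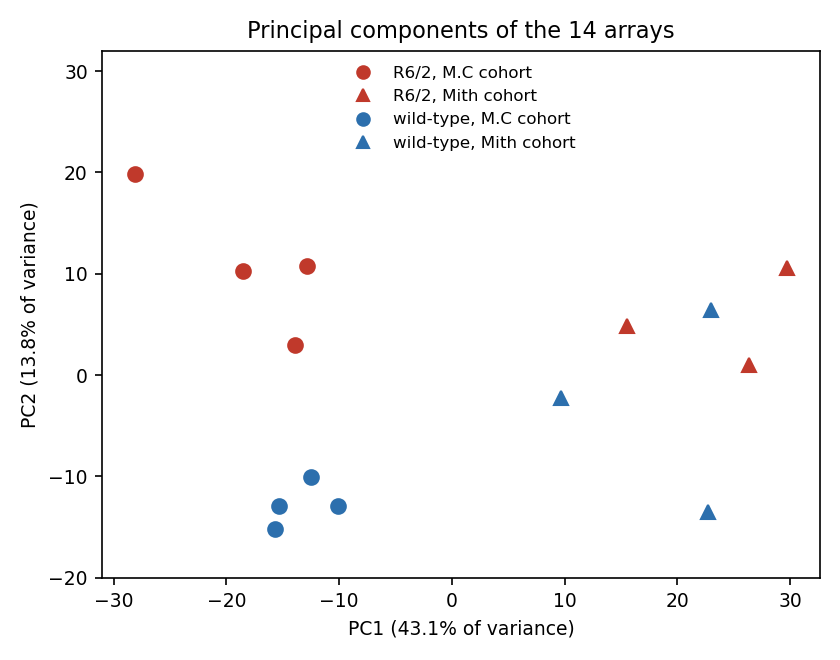
Position of the 14 arrays on principal components 1 (43.1% of the variance) and 2 (13.8%), with genotype and cohort marked. The cohorts lie apart on component 1.

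The main comparison asked which transcripts differ between R6/2 and wild-type striatum at this age. As lists, shared and indirect-pathway genes of striatal projection neurons were lower in R6/2, while the direct-pathway list was not called. Lists of myelin, activity-induced transcription, calcium handling and cholesterol synthesis genes were lower as well. Among the largest falls, Ryr1, an intracellular calcium release channel, was at 47.4% of the wild-type signal (-1.08 ± 0.10, adjusted p = 5.93e-05). Penk, the precursor of enkephalin, was at 54.0% (-0.89 ± 0.11, adjusted p = 8.87e-04). Ppp1r1b, a phosphatase inhibitor that relays dopamine and cyclic AMP signals, was at 57.2% (-0.80 ± 0.13, adjusted p = 0.00437). Rises were smaller, as with Pcbd2, an enzyme that regenerates the pterin cofactor of amino acid hydroxylases, at 131% of wild-type (0.39 ± 0.07, adjusted p = 0.00699).

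In all, 578 of 22626 probe sets were called, 2.55%, and 496 of these, 85.8%, were lower in R6/2. They stood for 315 genes, 257 lower and 58 higher. At an unadjusted p under 0.05 there were 3444 probe sets where 1131.3 would be expected by chance. The count rested on single arrays. It came to 280 without wild-type replicate 3, 295 without wild-type replicate 4, 295 without R6/2 replicate 1, 310 without wild-type replicate 7, 341 without R6/2 replicate 7, 370 without wild-type replicate 1 and 384 without R6/2 replicate 3, and rose to 879 without wild-type replicate 5. Without R6/2 replicate 4, the array that stood apart, it was 821, with 198 rises where all arrays gave 82, and 75.9% of calls were falls. After quantile normalization there were 131 rises, and 76.9% of calls were falls. Rises ran from 29 to 198 with 1 array left out. With the Actb 3′ minus 5′ difference as a covariate 56 probe sets passed, 54 of them lower, and all 578 kept their sign.

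The other large falls held several genes enriched in striatal neurons. Kcnip2, a potassium channel partner, fell by 0.95 ± 0.18, and its other probe set gave -0.02. Pde10a, a cyclic nucleotide phosphodiesterase, fell by 0.92 ± 0.17. Arpp19, a phosphoprotein regulated by cyclic AMP, fell by 0.92 ± 0.14, its 3 probe sets running from -0.92 to -0.12. Arpp21, another phosphoprotein regulated by cyclic AMP, fell by 0.84 ± 0.13, while another of its probe sets gave 0.02. Rasgrp2, an exchange factor for Rap, fell by 0.85 ± 0.17, and Rasd2, a small GTPase, fell by 0.82 ± 0.11. Coch, a secreted matrix protein, fell by 0.87 ± 0.12. Nnat, a small membrane protein of developing neurons, fell by 0.80 ± 0.18, and Ugt8a, which makes the galactolipids of myelin, fell by 0.79 ± 0.11. For Ryr1, Penk, Arpp19, Coch, Arpp21, Rasd2 and Ugt8a every wild-type array lay above every R6/2 array in both cohorts. These genes were taken from the largest falls, so this order is not a further test of them. With the Actb covariate 6 of these falls lost their call. Kcnip2 went to -0.50 ± 0.17 and Pde10a to -0.49 ± 0.15, while Arpp21 was at -0.75 ± 0.17, Rasgrp2 at -0.75 ± 0.22, Ppp1r1b at -0.64 ± 0.17 and Nnat at -0.84 ± 0.24, with larger SE. Over all 496 falls the median went from -0.39 to -0.33 and the median SE from 0.083 to 0.101.

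The 12 largest rises had no shared list. The largest, Atad2b, a bromodomain protein, rose by 0.40 ± 0.10 (adjusted p = 0.0446), but its call was lost in 12 of 14 fits with 1 array left out. Mrpl39, a mitochondrial ribosomal protein, rose by 0.35 ± 0.06 (adjusted p = 0.00495). Rgs19, a regulator of G protein signalling, rose by 0.37 ± 0.07, and Pcdhb9, a protocadherin, by 0.38 ± 0.08. Zswim7 (0.35), Nagk (0.35), Cdkl2 (0.34), Antkmt (0.32), Dpysl4 (0.32), Mea1 (0.31) and Sdr42e1 (0.31) were the others besides Pcbd2. None of the 12 kept its call with the Actb covariate, where their median went from 0.35 to 0.25 and the median SE from 0.071 to 0.084. Of the 53 named genes called, 33 kept the call in every fit with 1 array left out. Of the 14 fits, the call was lost in 12 for Atad2b, 11 for Nagk and Grin2c, 10 for Mea1, Nos1, Gad1 and Msmo1, 9 for Per1 and Rph3a, 8 for Idi1, 7 for Sst, Hmgcs1 and Cox7c and 6 for Kcnc1. It was lost in 4 for Syt1 and Hsp90b1, 3 for Antkmt and Olig2, and 2 for Nnat and Cdkl2.

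**Figure D2:**
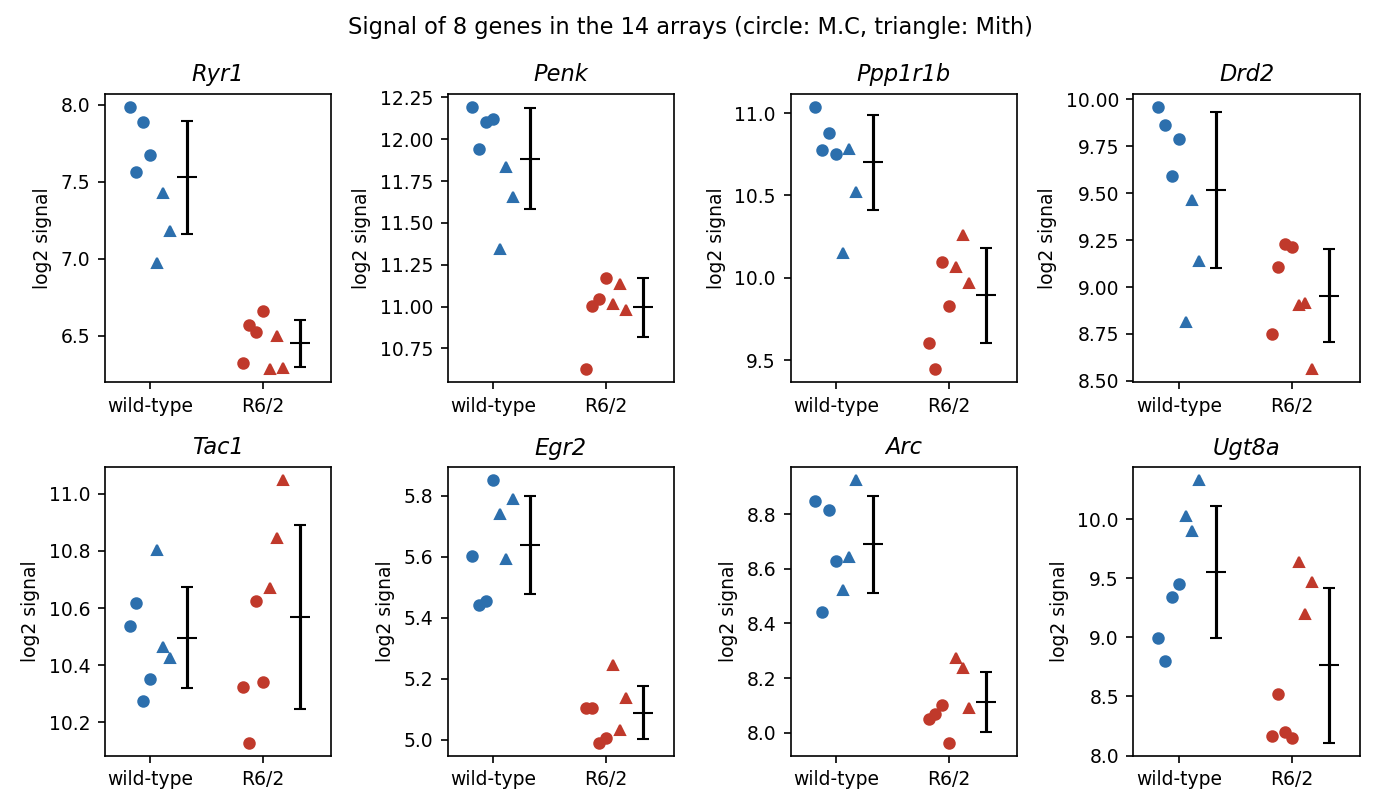
Log2 signal of named genes on each array by genotype and cohort, with group means. Ryr1 lay at 6.45 in R6/2 against 7.53 in wild-type, while Tac1 was 10.57 against 10.50.

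Shared projection neuron genes moved together. Of 15 measured, 11 fell, 0 rose and 4 did not pass, and 15 fell when adjusted over the list alone. The median change was -0.61 (camera adjusted p = 4.18e-23, and adjusted p = 0.0240 with an estimated correlation). Besides the genes above, Pde1b fell by 0.69, Rgs9 fell by 0.61 and Cnr1, the cannabinoid receptor, fell by 0.57 ± 0.10, to 67.5% of wild-type. Bcl11b and Meis2, transcription factors of these neurons, were at -0.43 and -0.29 and did not pass. The list's median was -0.80 in M.C and -0.37 in Mith. Wild-type replicate 5 had a mean of -0.26 for this list, while the other wild-type arrays lay between 0.26 and 0.56. RNA quality differed between the genotypes as given above, and with the Actb covariate the median was -0.50 and the list was still called, while Cnr1 was at -0.45 ± 0.12 (adjusted p = 0.149).

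The indirect and direct pathway genes parted. All 3 measured indirect-pathway genes fell, in the whole data and when adjusted over the list alone: Penk, Drd2, the dopamine receptor of these cells, at 67.7% of wild-type (-0.56 ± 0.11, adjusted p = 0.0122), and Plxdc1 (-0.29 ± 0.05). Their median was -0.56 (camera adjusted p = 1.75e-07, and adjusted p = 0.0114 with an estimated correlation). Of 7 direct-pathway genes 0 passed and 1 fell when adjusted over the list alone, and the median was -0.06 (camera adjusted p = 0.401). The cohorts went opposite ways. The list's median was -0.09 in M.C (camera adjusted p = 0.0409, but adjusted p = 0.143 with an estimated correlation). In Mith it was 0.06 (camera adjusted p = 0.254). Tac1, the substance P precursor, was at 0.07 ± 0.10 (adjusted p = 0.787), with -0.09 in M.C and 0.29 in Mith. Pdyn, the dynorphin precursor, was at -0.33 (adjusted p = 0.0537) and Isl1 at 0.16. The indirect-pathway mean changed by -0.54 ± 0.07 relative to the direct-pathway mean, exact permutation p = 0.00143 and adjusted p = 0.00429. The shared list changed by -0.60 ± 0.10 relative to it, exact permutation p = 0.00286 and adjusted p = 0.00429. These contrasts were among 3 chosen after the data were seen. With the Actb covariate the indirect-pathway list was still called and Penk kept its call, while Drd2 was at -0.44 ± 0.14 (adjusted p = 0.228) and Plxdc1 at -0.27 ± 0.07 (adjusted p = 0.143). Neither Drd1 nor Adora2a had a probe set with a single symbol.

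Interneuron genes fell as a list. Of 10 measured, 3 fell and 3 fell when adjusted over the list alone, and the median was -0.21 (camera adjusted p = 1.03e-04, and adjusted p = 0.0240 with an estimated correlation). They were Slc18a3, the vesicular acetylcholine transporter, at -0.35 ± 0.07, Sst, somatostatin, at -0.31 ± 0.07, and Nos1, neuronal nitric oxide synthase, at -0.32 ± 0.08. Quantile normalization ended the call of Nos1. With the Actb covariate the list was still called, but these genes were not: Slc18a3 was at -0.34 ± 0.09 (adjusted p = 0.149), Sst at -0.37 ± 0.09 (adjusted p = 0.127) and Nos1 at -0.40 ± 0.10 (adjusted p = 0.138).

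Genes of signalling and excitability fell in part. Of 21 calcium handling genes 8 fell, 10 when adjusted over the list alone, with a median of -0.29 (camera adjusted p = 5.61e-12, and adjusted p = 0.0159 with an estimated correlation). Besides Ryr1 they included Atp2b2, a plasma membrane calcium pump, at -0.51 ± 0.08, and Atp2a2, the pump of the endoplasmic reticulum, at -0.45 ± 0.07. Of 15 potassium channel genes 6 fell, 9 when adjusted over the list alone, with a median of -0.22 (camera adjusted p = 5.82e-07, and adjusted p = 0.0240 with an estimated correlation). Examples were Kcnip2, Kcnab1 at -0.44 ± 0.08 and Kcnc1 at -0.39 ± 0.09. Of 8 GABA receptor genes 1 fell, 4 when adjusted over the list alone, with a median of -0.17 (camera adjusted p = 7.86e-04, and adjusted p = 0.0305 with an estimated correlation). That gene was Gabrd, a subunit of extrasynaptic receptors, at 59.8% of wild-type (-0.74 ± 0.10, adjusted p = 0.00152). With the Actb covariate the GABA receptor list was no longer called, while the calcium and potassium channel lists were. Ryr1, Atp2a2 and Gabrd kept their calls there, while Atp2b2 was at -0.48 ± 0.11, Kcnab1 at -0.42 ± 0.11 and Kcnc1 at -0.27 ± 0.11 and were not called.

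Immediate early genes, which neurons induce on activity, fell as a list in animals that had all been injected. Of 15 measured 6 fell, 8 when adjusted over the list alone, with a median of -0.18 (camera adjusted p = 1.56e-10, and adjusted p = 0.00497 with an estimated correlation). Egr2 fell to 68.3% of wild-type (-0.55 ± 0.07, adjusted p = 8.87e-04), Arc to 67.0% (-0.58 ± 0.07, adjusted p = 9.62e-04) and Egr1 to 63.6% (-0.65 ± 0.10, adjusted p = 0.00318). Homer1 at -0.64, Dusp1 at -0.41 and Nr4a1 at -0.38 also fell, while Fos was at -0.08 (adjusted p = 0.719). Egr2 was at -0.54 in M.C and -0.57 in Mith, and the list's median was -0.20 in each cohort. The list, Egr2 and Arc were still called with the Actb covariate, while Egr1 was at -0.63 ± 0.14 (adjusted p = 0.0738).

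Myelin genes fell unevenly. Of 9 mature oligodendrocyte genes 5 fell, 6 when adjusted over the list alone, with a median of -0.30 (camera adjusted p = 3.57e-09, and adjusted p = 0.0366 with an estimated correlation). Ugt8a, Cldn11, a tight junction protein of myelin, at -0.68 ± 0.12, and Mobp, a myelin protein, at -0.58 ± 0.11, fell most, and Cnp and Mag fell as well, at -0.35 and -0.30. Mbp and Mog, also myelin proteins, were at -0.12 and -0.04 and did not pass. The medians were -0.33 in M.C and -0.36 in Mith. The list, Ugt8a and Mobp were still called with the Actb covariate, while Cldn11 was at -0.72 ± 0.15 (adjusted p = 0.0727). Thalamic genes, of bordering tissue, moved with the list in Mith: their medians were -0.56 in Mith and -0.09 in M.C. Their means and those of the myelin list were 0.82 and 0.59 in wild-type replicate 7, 0.73 and 0.47 in wild-type replicate 5 and -0.20 and -0.02 in R6/2 replicate 6. R6/2 replicate 7 was at 0.04 and 0.21. Wild-type replicate 6 (0.25 and 0.57) and R6/2 replicate 5 (0.19 and 0.32) lay close in thalamic genes and further apart in myelin genes. Between the cohorts the medians were -0.40 and -0.81, M.C minus Mith. Of 6 precursor genes 1, Olig2, fell by 0.27 ± 0.06 (-0.24 ± 0.08 and not called with the Actb covariate), and 3 fell when adjusted over the list alone, with a median of -0.18 (camera adjusted p = 0.0102, but adjusted p = 0.0740 with an estimated correlation). The mature list changed by -0.23 ± 0.06 relative to the precursor list, exact permutation p = 0.00429 and adjusted p = 0.00429.

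Cholesterol synthesis genes fell as a list. Of 16 measured 3 fell and 13 did not pass, and 9 fell when adjusted over the list alone, with a median of -0.25 (camera adjusted p = 5.63e-08, and adjusted p = 0.0240 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, was at -0.48 ± 0.11, Msmo1 at -0.40 ± 0.10 and Idi1 at -0.37 ± 0.09. The calls of these 3 were lost in 7, 10 and 8 of 14 fits with 1 array left out. The list's median was -0.22 in M.C and -0.18 in Mith, and -0.26 with the Actb covariate, where the list was still called. With that covariate Hmgcs1 was at -0.54 ± 0.14, Msmo1 at -0.51 ± 0.13 and Idi1 at -0.45 ± 0.11, and none was called. Mature oligodendrocyte genes moved with it: wild-type replicate 7 was highest of all arrays in both lists (0.28 for cholesterol and 0.59 for oligodendrocyte genes), R6/2 replicate 1 was at -0.32 and -0.50, R6/2 replicate 4 was at -0.30 and -0.56, and both lists had a median below 0 in M.C relative to Mith, -0.27 and -0.81.

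**Figure D3:**
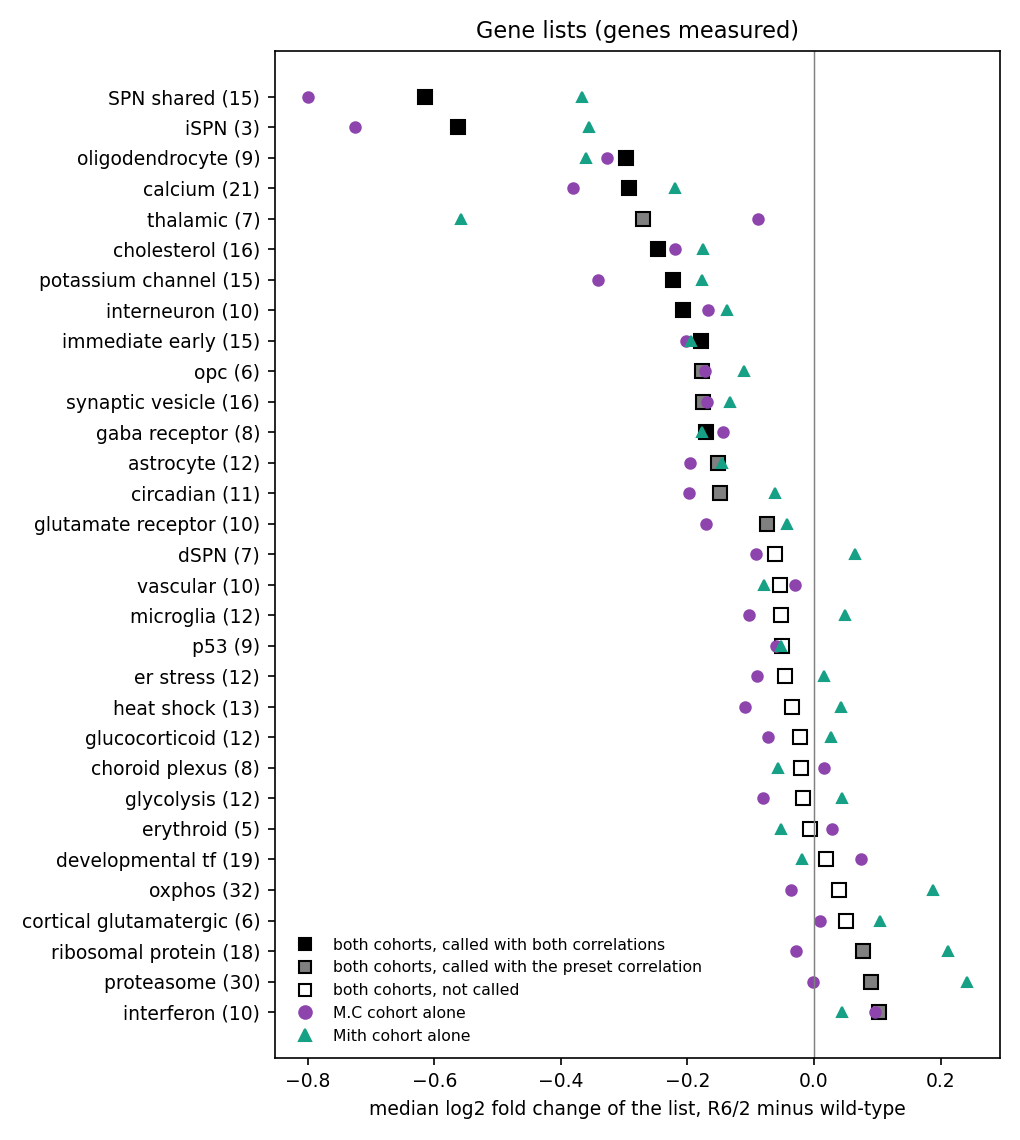
Median log2 fold change, R6/2 minus wild-type, of each of the 31 gene lists over both cohorts and in each cohort alone, with the number of genes measured. Filled squares mark the 18 lists called, black for the 9 that were also called with an estimated correlation; the shared projection neuron list lies lowest, at -0.61.

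A further 8 lists were called with the preset correlation and not with an estimated one. Thalamic neuron genes, of a neighbouring tissue, had a median of -0.27 with 0 of 7 called and 5 lower when adjusted over the list alone (camera adjusted p = 1.19e-04, but adjusted p = 0.143 with an estimated correlation), and their medians were -0.09 in M.C and -0.56 in Mith. Astrocyte genes had a median of -0.15 with 0 of 12 called and 5 lower when adjusted over the list alone (adjusted p = 0.0843 with an estimated correlation). Synaptic vesicle genes had a median of -0.18, and 3 of 16 fell, 7 when adjusted over the list alone (adjusted p = 0.169 with an estimated correlation). These were Syt1, the calcium sensor of release, at -0.59 ± 0.13, Rph3a at -0.46 ± 0.11 and Gad1, a GABA-synthesising enzyme, at -0.29 ± 0.07. They were at -0.24 ± 0.10 (adjusted p = 0.381), -0.22 ± 0.11 (adjusted p = 0.470) and -0.28 ± 0.10 (adjusted p = 0.287) with the Actb covariate. Circadian genes had a median of -0.15, and 1 of 11, Per1, fell by 0.24 ± 0.06, 2 when adjusted over the list alone (adjusted p = 0.0669 with an estimated correlation). Glutamate receptors had a median of -0.07, and 2 of 10 fell, also 2 when adjusted over the list alone (adjusted p = 0.111 with an estimated correlation): Grik2, a kainate receptor subunit, at -0.33 ± 0.06, and Grin2c, an NMDA receptor subunit, at -0.20 ± 0.05. Per1, Grik2 and Grin2c were at -0.14, -0.23 and -0.23 with the Actb covariate and were not called.

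The 3 called lists that lay higher in R6/2 had no member called, 0 also when adjusted over the list alone. The 30 proteasome subunits had a median of 0.09 (camera adjusted p = 0.00440, but adjusted p = 0.535 with an estimated correlation), with -0.0021 in M.C and 0.24 in Mith, and -0.016 with the Actb covariate. The 18 ribosomal proteins had a median of 0.08 (adjusted p = 0.534 with an estimated correlation), with -0.03 in M.C and 0.21 in Mith. The 10 interferon-stimulated genes had a median of 0.10 (camera adjusted p = 0.0358, but adjusted p = 0.151 with an estimated correlation), and quantile normalization ended their call. With the Actb covariate the oligodendrocyte precursor, glutamate receptor, synaptic vesicle, ribosomal protein and interferon lists were no longer called.

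The other lists were not called. Their medians and camera adjusted p were 0.05 and 0.302 for 6 cortical glutamatergic genes, -0.02 and 0.666 for 8 choroid plexus genes, -0.0064 and 0.935 for 5 erythroid genes, -0.05 and 0.111 for 12 microglia genes, and -0.05 and 0.217 for 10 vascular genes. Glycolysis (12 genes) had -0.02 and 0.345, developmental transcription factors (19 genes) 0.02 and 0.475, and p53 targets (9 genes) -0.05 and 0.142. These lists had 0 members called by limma, and also 0 when adjusted over the list alone. Of 12 glucocorticoid-responsive genes Per1 fell, 2 when adjusted over the list alone (median -0.02, adjusted p = 0.196). Of 13 heat shock genes Cryab, a small heat shock protein of glia, fell by 0.55 ± 0.09, 2 when adjusted over the list alone (median -0.03, adjusted p = 0.0515), and another probe set of Cryab gave 0.03. Of 12 unfolded protein response genes Hsp90b1, a chaperone of the endoplasmic reticulum, fell by 0.48 ± 0.11, also 1 when adjusted over the list alone (median -0.05, adjusted p = 0.142). Of 32 respiratory chain genes Cox7c rose by 0.25 ± 0.06, 2 when adjusted over the list alone (median 0.04, adjusted p = 0.0682), and its other probe set gave 0.02. Cryab kept its call with the Actb covariate, while Per1, Hsp90b1 (-0.32 ± 0.12) and Cox7c (0.31 ± 0.07) did not.

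Of the genes always looked at, 3 more were not called. Htt, the mouse gene, was 7.90 ± 0.06 (SD, n = 7) in R6/2 and 7.92 ± 0.03 (SD, n = 7) in wild-type, a change of -0.018 ± 0.044, adjusted p = 0.899 with limma. Its probe set does not check the transgene. Bdnf, a neurotrophin supplied to the striatum by the cortex, was at -0.0070 ± 0.067 (adjusted p = 0.975), and Ppargc1a, a regulator of mitochondrial genes, at -0.38 ± 0.15 (adjusted p = 0.226), its 5 probe sets running from -0.38 to -0.0045.

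The comparison was repeated within each cohort. In M.C, 558 probe sets were called, 523 lower and 35 higher, for 279 genes. Ryr1 changed by -1.26, Penk by -1.13 and Ppp1r1b by -1.12 there. In Mith the values were -0.84, -0.57 and -0.39, and limma called 0 probe sets, with 2008 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0846. The M.C count was 242 without R6/2 replicate 1, 272 without wild-type replicate 4, 287 without wild-type replicate 3, 295 without wild-type replicate 1, 339 without wild-type replicate 2 and 962 without R6/2 replicate 4. The Mith count was 13 without wild-type replicate 5 and 6 without wild-type replicate 6.

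Genes called in M.C moved the same way in Mith for the most part. Of 262 genes lower in M.C 224 were negative in Mith, and of 17 higher 14 were positive, so 85.3% kept their sign. Permuted labels gave up to 89.2% for those genes. The genes lower in M.C had a median of -0.51 there and -0.18 in Mith. They were chosen by their call in M.C, which by itself favours a larger value there. Of the 279 genes 73 had the same sign with an unadjusted p under 0.05 in Mith and 1 the opposite sign, where 11.2 would be shared in direction by independent lists. This count was not taken under permuted labels, and genes that move together widen its chance range, so 11.2 is only a guide. Across all 12393 genes, which are not independent replicates, Pearson's r of the cohorts' fold changes was 0.224 and Spearman's rho 0.118. Permuted labels gave r from -0.326 to 0.338, and 6 of 100 reached the observed value.

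**Figure D4:**
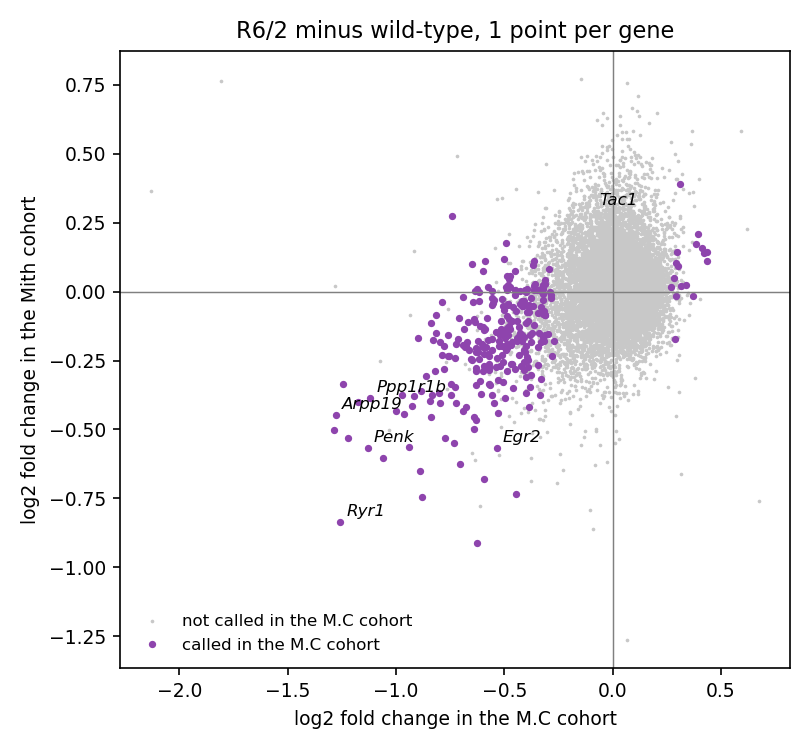
Log2 fold change, R6/2 minus wild-type, of each gene in the Mith cohort against that in the M.C cohort. Of 262 genes lower in M.C, 224 lie below 0 in Mith; Pearson's r over all 12393 genes is 0.224.

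The difference of the genotype effect between cohorts was tested with an interaction term. limma called 0 probe sets, with 2213 at an unadjusted p under 0.05 and a smallest adjusted p of 0.111. The largest call counts on leaving out an array were 7 without wild-type replicate 6 and 2 without R6/2 replicate 4. For Penk the difference, M.C minus Mith, was -0.56 (adjusted p = 0.352), and for Ppp1r1b -0.73 (adjusted p = 0.340).

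The cohorts themselves differed widely with genotype as a term. limma called 7312 probe sets, 32.3% of those tested, 3465 higher and 3847 lower in M.C, for 3851 genes. The largest changes higher in M.C were Taok1, a kinase, by 1.85 ± 0.07 (adjusted p = 1.63e-10), Ddx6, an RNA helicase, by 1.77 ± 0.12, Galnt2 by 1.41 ± 0.11, Atp8a1 by 1.40 ± 0.11 and Rap2b by 1.39 ± 0.11. Lower in M.C were Prmt1, an arginine methyltransferase, at -1.43 ± 0.17, Resp18 at -1.42 ± 0.28, Rpl22l1 at -1.32 ± 0.22, Rora at -1.31 ± 0.16 and Zic1 at -1.30 ± 0.30. Of 9 mature oligodendrocyte genes 8 were lower in M.C, with a median of -0.81 (camera adjusted p = 3.32e-06). Respiratory chain genes had -0.27, ribosomal proteins -0.32, proteasome subunits -0.24, cholesterol genes -0.27 and thalamic genes -0.40 between the cohorts. None of the lists was called between cohorts with an estimated correlation, the lowest adjusted p being 0.423. The labels do not separate the drug study from the batch of arrays, so these cannot be told apart.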

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

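The tests of the 3 patterns below were chosen after the results were seen, as was the look at single arrays within them, while the other assignments of the arrays to groups were planned before the data were examined.

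Wild-type replicate 5 had a mean of -0.26 for the shared projection neuron list, against 0.26 to 0.56 on the other wild-type arrays, with Kcnip2 at 7.48 and Rasgrp2 at 7.78, both far below its group, and a ribosomal protein mean of 0.30, above it. R6/2 replicate 4 stood apart in the unfolded protein response list (-0.13), the developmental transcription factor list (0.14), Nagk (7.54) and Cdkl2 (6.94). R6/2 replicate 1 stood apart in the interferon list (0.16), Penk (10.6), Egr1 (10.2) and Gabrd (7.73). R6/2 replicate 2 stood apart in the 18S control (10.4), Kcnip2 (6.42) and Htt (7.78). The astrocyte list stood apart in R6/2 replicate 5 (0.20) and wild-type replicate 7 (0.27), which also did so in Nagk (7.91) and Syt1 (10.6). Wild-type replicate 2 stood apart in the 18S control (12.1) and Plxdc1 (7.12), and wild-type replicate 4 in Egr1 (11.7). These were 22 values in 218 groups of 7 arrays tested with Dixon's ratio, where chance gives about 1 in 20 groups, or 10.9. Each group held arrays of both cohorts and the cohort difference was not taken out, so this chance count is only a guide.

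The genotype effect on 12 lists differed between the cohorts by camera on the interaction with the preset correlation. The adjusted p was 1.83e-09 for shared projection neuron genes, 0.00743 for direct-pathway genes, 0.0405 for cortical glutamatergic genes, 0.00425 for microglia, 0.00149 for calcium handling, 0.00671 for heat shock, 4.71e-07 for the proteasome, 4.55e-04 for the respiratory chain, 0.0396 for glycolysis and 0.00425 for ribosomal proteins, each lower in M.C relative to Mith. It was 6.15e-06 for thalamic genes and 0.0392 for developmental transcription factors, each higher in M.C relative to Mith. None was called with an estimated correlation, the lowest adjusted p being 0.235.

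Chance as the source of the calls was tested with other assignments of the arrays. For the genotype effect 1 of 100 assignments within cohorts, the real one, gave as many as 578 probe sets, and the highest other gave 3. This argues against chance, at the smallest share that 100 assignments can give. In M.C 1 of 35 did so, with 558 against a highest other of 1. Chance is argued against there too, at the smallest share that 35 assignments can give. In Mith the 10 possible assignments are too few for such a share; the real one gave 0 and the highest other 296. That other one exchanges wild-type replicate 5 with R6/2 replicate 6, and points to a structure of these samples. For the interaction the real count was 0, which each of the 100 assignments had to reach (the highest gave 15), so this says nothing about chance. For the cohort difference 1 of 100 gave as many as 7312, with 3240 as the highest other, which also argues against chance. For the gene lists at the preset correlation 2 of 100 gave as many as 18, the real one and 1 other that also gave 18, so the count of 18 lies at the edge of what chance gave and not beyond it. With an estimated correlation 9 lists were called and 0 in any other assignment drawn.

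Falls outnumbered rises, 496 to 82. RNA quality, as the Actb 3′ minus 5′ difference tracks it, is argued against as the whole source by the fit with that difference as covariate. There the 496 probe sets kept a median of -0.33, from -0.39 (-0.39 to -0.27 with 1 array left out). Their calls were largely lost, and the cause of this was not tested. The measure tracks genotype within cohorts (r = 0.634) and the median SE grew from 0.083 to 0.101. For some genes the fold shrank and the SE did not grow, as with Kcnip2 (-0.95 ± 0.18 to -0.50 ± 0.17) and Syt1 (-0.59 ± 0.13 to -0.24 ± 0.10). The 496 were chosen in the fit without the covariate, 1 such measure tracks RNA quality with noise, and the Gapdh difference was not used as a covariate. A narrower range of signals on the R6/2 arrays of M.C as the whole source is argued against by quantile normalization, after which 76.9% of calls were falls (67.9% to 81.7% with 1 array left out). A part played by RNA quality stays open, and so does a biological loss of transcripts in R6/2, which may account for the rest.

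Genes were called in M.C and 0 in Mith, though the interaction called 0 as well. RNA quality as a source of this was not tested. The Gapdh 3′ minus 5′ means, R6/2 against wild-type, were 0.337 against 0.053 in M.C and 0.058 against -0.0095 in Mith. The Actb means were 0.577 against 0.324 and 0.649 against 0.439. After quantile normalization, which gives every array the same range, 371 probe sets were called in M.C and 0 in Mith. Fewer arrays in the Mith cohort are argued against only at the fold changes of M.C. There 0 of the 16 subsets with 3 against 3 arrays had 0 calls (15 to 636). The subsets share arrays and do not test the smaller fold changes seen in Mith. In the simulation 34 of 100 changes of 0.5 were recovered within Mith and 71 within M.C. Fewer arrays acting on smaller fold changes therefore stay open. A wider spread in Mith over all probe sets is argued against by a ratio of median residual SD of 1.03 (0.96 to 1.03 with 1 array left out). That ratio does not measure the spread of the genes called in M.C. Means of the shared projection neuron list ran from -0.26 to 0.32 on the Mith wild-type arrays and from 0.39 to 0.56 on those of M.C. On the R6/2 arrays they ran from -0.38 to -0.09 in Mith and from -0.58 to -0.17 in M.C. A wider spread of such genes in Mith stays open. A wrong genotype label on wild-type replicate 5 cannot be told apart from a true wild-type array: it lay above all R6/2 arrays of Mith in 87 of the 262 genes lower in M.C (wild-type replicates 6 and 7 in 179 and 193), a count that 22 of 10000 draws at 1 in 4 reached (at most 97), and genes that move together widen that range. Against a wrong label, it lay with the wild-type for Egr2 (5.74 against at most 5.24), Arc (8.52 against 8.27), Ryr1 (6.97 against 6.49), Ugt8a (10.03 against 9.64) and Cldn11 (8.44 against 7.97), genes picked after their values were seen. Other counts were low. It lay above all R6/2 arrays of Mith in 4 of 15 projection neuron genes (13 and 14 for wild-type replicates 6 and 7). It did so in 8 of the 20 genes lower in M.C with the smallest p. The r of the cohorts' fold changes over genes called in M.C was 0.593 as labelled and 0.472 with wild-type replicate 5 and R6/2 replicate 6 exchanged. That exchange relabels 2 arrays, so it cannot test a wrong label on wild-type replicate 5 alone. A smaller genotype effect in the Mith animals also stays open, as the interaction of the shared projection neuron mean was -0.54 ± 0.20 (SE), and -0.36 ± 0.15 without wild-type replicate 5. Bordering tissue was not tested for this pattern. Thalamic means in Mith were 0.73, 0.25 and 0.82 in wild-type replicates 5 to 7 and 0.19, -0.20 and 0.04 in R6/2 replicates 5 to 7. Wild-type replicate 5 was thus high in thalamic genes, but so was wild-type replicate 7, whose projection neuron mean was 0.26.

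Myelin genes fell as a list in R6/2. A smaller share of oligodendrocytes as the whole source stays open. Of the 9 members 5 lay over 2 SE from the mean of the members, with an SD of 0.267 between members and a median SE of 0.093. But probe sets of 1 gene also differed, from -0.79 to -0.53 for Ugt8a and from -0.84 to -0.58 for Mobp. Members may therefore scatter this far under an equal change of cells, so the test cannot decide. RNA quality, as the Actb difference tracks it, is argued against as the whole source by a median of -0.36 with the Actb covariate, from -0.30 (-0.42 to -0.32 with 1 array left out). Bordering thalamic tissue, as the thalamic list tracks it, is argued against as the whole source. With the mean of that list as covariate the median was -0.27 (-0.35 to -0.20 with 1 array left out, median SE 0.115, 2 members called). A mean of 7 genes tracks such tissue with noise, and a part played by it stays open. Other bordering tissue, which this list does not track, was not tested and stays open as well. A change of transcription within oligodendrocytes may be a candidate, and it was not tested apart from a smaller share of these cells.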

How the results depend on the processing

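The fit by quantile normalization without R6/2 replicate 4, the permutation of the quality measures within cohorts and the contrasts between lists were chosen after seeing the data; all other alternatives were fixed before the data were examined, and unless stated the cause was not tested. Pseudocounts were not run, as the values were already on the log2 scale. No paired analysis was possible because the labels give no numbers that match R6/2 with wild-type animals. Array signals near background limit the dim probe sets.

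The genotype effect of 578 probe sets became 100 (9 rises, 91 falls, 55 genes) with no cohort term, where the cohort difference enters the spread. It became 1333 (273 rises, 1060 falls, 691 genes) with array weights and 56 (2 rises, 54 falls, 96.4% falls, 31 genes) with the Actb covariate. At a threshold of 0.01, stricter by construction, it was 131 (7 rises, 124 falls, 66 genes). With 1 probe set per gene, which tests fewer, it was 344 with 282 falls. Rises were 131 after quantile normalization, 22 among the brightest probe sets and 35 in M.C alone. Mith alone had 0 probe sets, 0 rises, 0 falls, 0% falls and 0 genes. Quantile normalization without R6/2 replicate 4 gave 971 (312 rises, 67.9% falls, 502 genes). With 1 array left out, probe sets ran from 280 to 879, rises from 29 to 198, falls from 251 to 755 and genes from 146 to 459. M.C had 371 after quantile normalization and 242 to 962 with 1 array left out, Mith 0 to 13 and the interaction 0 to 7. The cohort difference was 4653 above the median signal, which tests fewer. Agreement between cohorts was r = 0.325 above the median signal. Lists called were 11 with the Actb covariate and 9 with an estimated correlation.

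Directions turned for small values. Bdnf was 0.0098 after quantile normalization, 0.011 as deposited, 0.11 with the Actb covariate, 0.027 in M.C alone and -0.061 to 0.021 with 1 array left out. Htt was 0.0090 after quantile normalization, 4.65e-04 as deposited, 0.022 with the Actb covariate and -0.031 to 0.0025 with 1 array left out. Tac1 was -0.091 in M.C alone. Proteasome genes had -0.016 with the Actb covariate and -0.0021 in M.C alone, and ribosomal proteins -0.029 in M.C alone.

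Of 57 named genes, direction and call held in 51 after quantile normalization, 53 as deposited, 56 with trended variances, 57 with array weights, 55 with Xist, 23 with no cohort term, 14 with the Actb covariate and 39 to 54 with 1 array left out, 33 of the 53 called ones being called in each of those fits; apart from the turns above, the others lost the call. Of 18 lists, 17 held after quantile normalization, 18 as deposited, 15 with fry and 16 to 18 with 1 array left out. The 10 genes named between cohorts held in all alternatives run.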

Other observations

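The further biology here was looked at after the results were seen. Genes of tissue that borders the striatum varied between arrays. Ttr, the main transcript of the choroid plexus, ran from 8.43 to 13.4 over the 14 arrays and did not differ by genotype, exact permutation p = 0.769. Thalamic neuron genes had fold changes in Mith from -1.26 for Prkcd to -0.11 for Lhx9, and from -0.26 for Slc17a6 to 0.12 for Lhx9 in M.C. None of the 7 was called by limma in either cohort or over both. The interaction of genotype with cohort for this list had a camera adjusted p = 0.235 with an estimated correlation.

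Among glial genes, Slc1a3 and Gja1, a glutamate transporter and a gap junction protein of astrocytes, were at -0.39 (adjusted p = 0.0510) and -0.48 (adjusted p = 0.0669) and were not called. Several myelin genes differed between the cohorts by more than between genotypes: Ugt8a was at -1.06 in M.C relative to Mith, Mog at -1.01 and Aspa at -0.81. The median change of all probe sets, R6/2 minus wild-type, moved with brightness. In M.C it was 0.05 for probe sets with a mean log2 signal under 6 and -0.08 for those over 10, and in Mith it was -0.0014 and 0.04.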
